A study of Mus musculus with 6 samples.

How the data were processed

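Expression was measured in total RNA of 6 mouse fetal livers at E14.5, 3 of Tmod3 knockout and 3 of wild type embryos, which the series text describes as independent embryos. Per the labels' protocols, RNA was extracted with Trizol and biotin-labelled from 6 ug of total RNA, and hybridised to Affymetrix MoGene 1.0 ST arrays. The deposited table holds 1 value per probe set and array, made with RMA per the submitters' processing notes, with no version given. RMA corrects the background, normalizes between arrays by quantiles and summarises each probe set. The log base is not given in the sources used here, and the deposited values were read as log2 from their range: raised from base 2, the highest value of each array lies between 3457 and 6451, below the scanner limit of 65535, and raised from base e it lies between 127417 and 313456, above it. Array medians of 1.36 to 1.43 are low for RMA values, and the upper parts of the 6 distributions differ, which a quantile step would leave alike. A further background step or another normalization is therefore not ruled out, and the size of every fold change is that of the deposited values. Arrays have no read depth.

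Probe sets were named through a platform annotation table. Of 28853 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 5443 were not named there. For 21698 of the probe sets with 1 symbol the Entrez identifier was found in a gene table of the assembly GRCm38.p6, and 0 symbols needed an update. That gene table was used only for names and for the order of neighbouring genes. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19938 genes, 998 of them with more than 1 probe set. No filter on dim genes was applied. Probe sets with several genes or none were left out, and 42 members of the fixed lists had no probe set of their own and were not analysed here.

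Knockout and wild type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariates, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists for pathways and cell types were fixed before the data were examined, and 28 lists with at least 3 measured genes were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over the list alone. For each list, 10000 random lists of the same size, each member replaced by a gene within 100 ranks of its mean level, gave the median of lists of like level. The mean level per list was compared with an exact permutation test, for which 3 against 3 arrays cannot give a p below 0.1. Genes near Tmod3 were counted against all others with Fisher's exact test. Replicates were compared before use: correlations over all probe sets were 0.980 to 0.981 within the knockout group and 0.978 to 0.990 within the wild type group, and 0.974 to 0.983 between groups, so no array was a copy of another. Knockout replicate 1 and wild type replicate 1 (0.983) correlated more closely than any pair of knockout arrays.

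Genes named in the text were chosen by a rule written before the data were examined. The rule takes Tmod3, then up to 15 genes per direction with an adjusted p under 0.05 and no overlap between groups, and where fewer than 5 pass in a direction it fills up to 10 genes by smallest p, said not to pass. The filling was likewise limited to genes with no overlap between groups. It also takes up to 4 members of each list by smallest p and the sex-linked check genes, while predicted genes and similar names are counted but not named. Other genes are said to be chosen after their values were seen.

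The gene and list tests were tested on simulated data with 19938 genes in 20 runs. For the knockout against wild type comparison, 73.9% of genes changed by 1 on the log2 scale and 97.1% of those changed by 2 were recovered, and 4.28% of calls were false. The simulated noise was normal and independent for each gene, with no difference between whole arrays. Changed genes were drawn at random from all genes, dim ones included. These shares may therefore not carry over to the real arrays, where Igfbp1 (+2.50) did not pass (limma adjusted p = 0.202). A list of 19 genes shifted by 0.5 was recovered in 100% of runs. Its simulated genes did not covary, while the estimated correlation within the hypoxia and glycolysis list was 0.237 in the real data. That share therefore cannot show how often a list of covarying genes is recovered or called falsely. Alternatives written before the data were examined were the replicate number as a block, leaving out each array, renewed quantile normalization, centring on the median, the mean of a gene's probe sets, filters on dim genes, an intensity trend with robust fitting, array weights, other thresholds, all probe sets, and leaving out sex chromosomes or the neighbours of Tmod3. Cyclic loess, a filter that keeps the 3988 genes with the highest means, that filter with quantile normalization, and a block of arrays with alike distributions were added after seeing the data. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.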

Results

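Gene expression was measured in fetal liver of mouse embryos at E14.5, when the liver is the main site of red cell formation. The comparison asked which transcripts differ when Tmod3 is missing. Tmod3 encodes tropomodulin 3, a protein that caps the pointed ends of actin filaments. The samples were 3 livers of Tmod3 knockout embryos, described by the submitters as small and from anemic embryos, and 3 livers of wild type embryos, all on the C57BL/6J background and each from a separate embryo. Each RNA was hybridised to 1 Affymetrix MoGene 1.0 ST array, a whole-transcript array with 28853 probe sets in the deposited table, and 19938 named genes were tested. The number of arrays limits the precision of every value below. Array medians lay between 1.36 and 1.43 on the log2 scale. The 90th percentile was 3.67, 3.82 and 3.68 in knockout replicates 1, 2 and 3, and 3.68, 4.07 and 4.13 in wild type replicates 1, 2 and 3. Among the 2545 genes with a mean level of at least 3, the median log2 fold change of knockout minus wild type was -0.25, while over all genes it was 0.01. By mean level it was -0.24 for genes from 3 to 4 and -0.28 for those from 4 to 5 and from 5 to 6. Lists that passed are therefore given beside random lists of like level, while single genes below are given without such a value.

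Tmod3 transcript was 8.33-fold lower in knockout liver as measured, with a level of 1.66 ± 0.60 (SD, n = 3) against 4.72 ± 0.21 (SD, n = 3) in wild type liver. The knockout arrays read 1.32, 2.36 and 1.30 and the wild type arrays 4.49, 4.78 and 4.90, so each array matched its genotype label. Knockout replicates 1 and 3 lay below the medians of their arrays (1.43 each), near the floor of the measurement, so the size of the loss is not known beyond the measured values. The log2 fold change was -3.06 with a standard error of 0.27 (limma adjusted p = 0.0225). The call did not hold without knockout replicate 1 (adjusted p = 0.0911), knockout replicate 3 (0.109), wild type replicate 2 (0.255) or wild type replicate 3 (0.0856). Which part of the gene is disrupted is not given in the sources used here.

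Besides Tmod3, Car3 and Hpgd fell in knockout liver. Car3, a cytosolic carbonic anhydrase, read 2.31 ± 0.12 against 4.08 ± 0.08 (SD, n = 3 each), a log2 fold change of -1.77 with a standard error of 0.11 (limma adjusted p = 0.00315). Hpgd, the enzyme that inactivates prostaglandins, read 3.52 ± 0.06 against 4.93 ± 0.21 (SD, n = 3 each), a log2 fold change of -1.41 with a standard error of 0.13 (limma adjusted p = 0.0225). The Car3 call ended without wild type replicate 2 (adjusted p = 0.0569). The Hpgd call held without wild type replicate 1 (0.0117). It ended without any other 1 array, namely knockout replicate 1 (0.0911), 2 (0.182) or 3 (0.115) or wild type replicate 2 (0.255) or 3 (0.0856). It also ended with an intensity trend and robust fitting together (0.0930). No gene passed the threshold in the higher direction. With limma, 3 of 19938 genes passed, all lower, and 1801 genes had an unadjusted p under 0.05, of which 1284 were lower and 517 higher. After the arrays were quantile normalized again, 7 genes passed, 4 higher (Aldoa, Ero1a, Fabp4 and Plod2) and 3 lower. Without wild type replicate 1 the count was 95, with 94 lower and 1 higher, without knockout replicate 1 it was 1, and without wild type replicate 2 it was 0. Wild type replicate 1 correlated more closely with knockout replicate 1 (0.983 over all probe sets) than with wild type replicate 3 (0.978).

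The genes next in rank did not pass the threshold. On the lower side, Serpinb6b had a log2 fold change of -1.0 and an adjusted p of 0.0852. Orc2, a subunit of the origin recognition complex, had -0.80, Lgals9, which encodes galectin 9, had -0.83, Alg14 had -0.83, Tex9 had -1.14 and Xpo7, which encodes a nuclear export receptor, had -1.15, each with an adjusted p of 0.103. Rfc4, a subunit of the clamp loader of DNA replication, had -0.95 (adjusted p = 0.104). On the higher side, the fatty acid binding protein gene Fabp4 had +1.21 and the angiogenic growth factor gene Vegfa +0.84, both with an adjusted p of 0.103. Plod2, a collagen lysyl hydroxylase, had +1.19, Rps28 +0.68, the glycolytic genes Pgk1 and Aldoa +1.32 and +1.31, the endoplasmic reticulum oxidase gene Ero1a +0.99, and Igfbp1, which encodes an insulin-like growth factor binding protein, +2.50, with adjusted p between 0.118 and 0.202. C1ql4 and Mfsd13a had +0.54 each (adjusted p = 0.202). All of these genes had their 3 knockout arrays on one side of the 3 wild type arrays, because only such genes could be named here. Over all genes the share without overlap was 13.2%, where chance gives 10%. Rps28 was covered by 7 probe sets and Pgk1 by 3, of which the brightest was used.

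**Figure D1:**
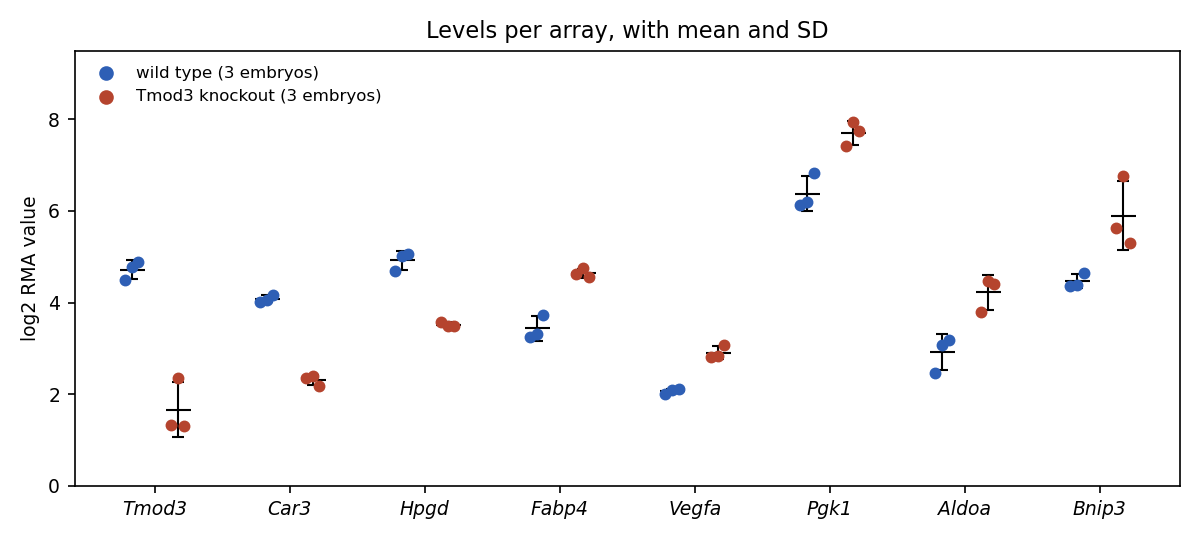
Log2 RMA values of 8 genes on each array (points), with the mean and SD of the 3 embryos per genotype (black bars). Tmod3, Car3 and Hpgd lie lower in all 3 knockout arrays; Fabp4, Vegfa, Pgk1, Aldoa and Bnip3 lie higher in all 3 but did not pass the threshold over all genes.

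Genes of the response to low oxygen and of glycolysis were higher in knockout liver as a list. The 19 measured members had a median log2 fold change of +0.43 (limma camera adjusted p = 4.9e-08), where random lists of like level had a median of -0.07. The call rests on a small preset correlation between genes, and the adjusted p was 0.505 with an estimated correlation. Without knockout replicate 2 the median was +0.23. Over the list, 7 members rose when adjusted over the list alone and 0 passed over all genes. Among the 7, Vegfa had a log2 fold change of +0.84, Pgk1, a kinase of glycolysis, +1.32, Aldoa, which encodes an aldolase, +1.31, and Bnip3, which encodes a mitochondrial protein of mitophagy, +1.43. The remaining 3 were Pfkp, Egln1 and Ldha, chosen for naming after their values were seen. The mean level over the list was 3.37 ± 0.25 in knockout and 2.89 ± 0.12 in wild type liver (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Each knockout array (3.11, 3.62 and 3.38) lay above each wild type array (2.80, 2.84 and 3.03).

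**Figure D2:**
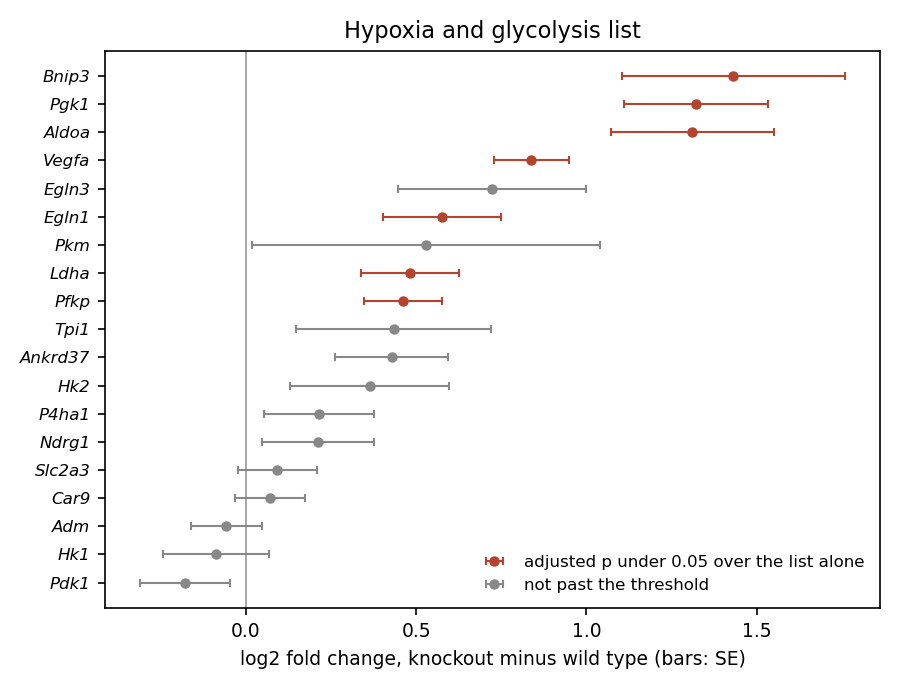
Log2 fold change (knockout minus wild type, x axis) of the 19 measured genes of the hypoxia and glycolysis list, with standard errors as bars. The 7 genes past the threshold when adjusted over the list alone are in red; Bnip3 has the largest value, +1.43.

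Genes of DNA replication and mitosis were lower in knockout liver as lists, as were well expressed genes in general. For the 23 genes of the G1/S transition and DNA replication the median log2 fold change was -0.33 (limma camera adjusted p = 8.2e-08), against -0.15 for lists of like level, and the adjusted p was 0.505 with an estimated correlation. Of these, 5 fell when adjusted over the list alone and 0 over all genes. They included Rrm1, a subunit of ribonucleotide reductase, with -0.75, the cyclin gene Ccne2 with -0.98, Pcna, the sliding clamp of DNA polymerase, with -0.50, and Gins2 of the replicative helicase with -0.54. The cyclin gene Ccnd2, chosen for naming after its value was seen, had +0.35, an unadjusted p of 0.0377, and did not pass over the list. The 23 genes of the G2/M phase and mitosis had a median of -0.34 (limma camera adjusted p = 3.0e-07), against -0.22 for lists of like level, and the adjusted p was 0.505 with an estimated correlation. No member of this list passed, whether adjusted over the list alone or over all genes (limma), and 8 had an unadjusted p under 0.05; Ccna2 had -0.61, Anln -0.50, Kif23 -0.41 and Aurka -0.45. After renewed quantile normalization the median was -0.12 for the G1/S list (adjusted p = 0.00549) and -0.13 for the G2/M list, whose call ended (0.0709). In mean level as deposited, each knockout array lay below each wild type array for both lists (two-sided exact permutation p = 0.1). After that normalization the groups overlapped for the G2/M list (exact permutation p = 0.3). The 12 inhibitors of cyclin-dependent kinases and other genes of cell cycle exit did not shift as a list (median -0.04, adjusted p = 0.815). Within that list, adjusted over the list alone, Cdkn1b (+0.42) and Btg1 (+0.38) rose and Cdkn2c (-0.54) fell, and Rbl1 had -0.44. None of the 3 passed over all genes.

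Erythroid gene lists were lower in knockout liver, as were well expressed genes in general. The 19 genes of the membrane skeleton and the red cell membrane had a median log2 fold change of -0.38 (limma camera adjusted p = 4.8e-06), against -0.22 for lists of like level, and the adjusted p was 0.505 with an estimated correlation. Here 5 members fell when adjusted over the list alone and 0 over all genes, among them Mpp1 (-0.85), Epb42 (-0.76), which encodes protein 4.2, the adducin gene Add1 (-0.60) and Rhag (-0.59). For the 24 genes of terminal maturation and enucleation the median was -0.25 (adjusted p = 0.000997), for the 19 genes of heme synthesis and iron uptake -0.12 (0.00445), for the 10 genes of adhesion in erythroblastic islands -0.18 (0.00639) and for the 16 erythroid transcription factors and receptors -0.12 (0.0216), each by limma camera. All 4 had an adjusted p of 0.505 with an estimated correlation. The exact permutation test on the mean level gave p = 0.2 for membrane and transcription factors, 0.3 for maturation and heme and 0.1 for adhesion. Knockout replicate 2 lay above wild type replicate 1 in mean level for membrane (4.17 against 4.07) and maturation (3.98 against 3.81). The same held for heme (4.32 against 4.16) and transcription factors (2.76 against 2.63), while the groups did not overlap for adhesion. Adjusted over the list alone, 3 maturation genes fell, namely Xpo7 (-1.15), Slc43a1 (-1.22) and Epb42, and 4 genes of heme and iron, namely Alas2, the first enzyme of erythroid heme synthesis (-0.63), Fech, which inserts iron into heme (-0.71), the transferrin receptor gene Tfrc (-0.67) and Tmem14c (-0.69). The adhesion gene Icam4 (-0.61) and the transcription factor genes Klf3 (-0.98) and Nfe2 (-0.56) also fell when adjusted over the list alone, and 0 of these genes passed over all genes. Chosen for naming after their values were seen, the ferritin gene Ftl1 of the heme list (+0.78) and Cited2 of the maturation list (+0.34) were higher at an unadjusted p under 0.05 but did not pass over their lists. Lists of like level had medians of -0.16 for maturation, -0.13 for heme, -0.09 for adhesion and -0.14 for transcription factors. After renewed quantile normalization the calls of the membrane (adjusted p = 0.0667), maturation (0.157), heme (0.137), adhesion (0.138) and transcription factor (0.693) lists ended. Their medians were then -0.11 for membrane, -0.06 for maturation, -0.03 for heme, -0.13 for adhesion and 0.00 for transcription factors. The heme call also ended without wild type replicate 3 (0.217 being its highest adjusted p when 1 array was left out), the adhesion call without the same array (0.116) and the transcription factor call without knockout replicate 1, knockout replicate 3 or wild type replicate 2 (up to 0.214). Some medians moved by over 1.5 times without 1 array: membrane to -0.25 without wild type replicate 2, and adhesion to -0.07 without wild type replicate 3. The maturation median was -0.41 without wild type replicate 1, -0.15 without knockout replicate 3 and -0.12 without wild type replicate 3. The heme median was -0.25 without knockout replicate 2 and -0.30 without wild type replicate 1, and that of transcription factors was -0.26 and -0.20 without these arrays and -0.05 without wild type replicate 2.

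The embryonic globin genes went both ways. Hba-x read 5.63 ± 0.26 against 4.30 ± 0.67 and Hbb-y 8.07 ± 0.27 against 6.62 ± 1.04, while Hbb-bh1 read 4.03 ± 0.48 against 5.24 ± 0.90 (SD, n = 3 each). Adjusted over the list alone, Hba-x and Hbb-y rose and Hbb-bh1 fell (limma adjusted p = 0.00661, 0.0176 and 0.0207), and 0 of the 3 passed over all genes. The groups overlapped for Hbb-y, as wild type replicate 3 (7.83) lay above knockout replicate 3 (7.76). Wild type replicates 1 and 2 read 6.05 and 5.98 for Hbb-y. For Hba-x the 3 wild type arrays read 3.88, 3.95 and 5.07. Without wild type replicate 3, which read 6.28 for Hbb-bh1 against 4.68 and 4.76 in the other wild type arrays, the log2 fold change of Hbb-bh1 was -0.69 in place of -1.21. The list did not pass (limma camera adjusted p = 0.156), but it passed without wild type replicate 3 (0.000878) and among the 3988 genes with the highest means (0.0232). With all arrays and genes the adjusted p was 0.550 with an estimated correlation. The 6 adult globin genes were covered only by probe sets shared between genes and were not analysed here.

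Markers of other liver cells moved in different directions. The 23 hepatoblast and hepatocyte markers had a median log2 fold change of -0.40 (limma camera adjusted p = 0.000338), against -0.17 for lists of like level, and the adjusted p was 0.539 with an estimated correlation. The plasma protein genes Apoh (-1.24), Vtn (-0.88), Ahsg (-1.15) and Apoa1 (-0.89) were the members with the smallest p, and 0 passed over the list alone or over all genes (limma; 7 had an unadjusted p under 0.05). The hepatocyte call ended without knockout replicate 3 (median -0.12, adjusted p = 0.0576), whose mean level over the list was 4.76 against 5.52 and 5.66 in the other knockout arrays, and without knockout replicate 2 the median was -0.66. Without knockout replicate 3, Vtn had -0.53, Ahsg -0.55 and Apoa1 -0.43. After renewed quantile normalization the hepatocyte median was -0.22. The 22 macrophage markers had a median of -0.18 (limma camera adjusted p = 0.00445), against -0.02 for lists of like level, and the adjusted p was 0.505 with an estimated correlation; Slc40a1, the iron exporter, had -0.36, Spic -0.85, C1qc -0.31 and Vcam1 -0.46, and 0 members passed (limma; 3 had an unadjusted p under 0.05). The groups overlapped for Spic and C1qc, and without knockout replicate 3 the values were -0.40 for Spic, -0.20 for C1qc and -0.23 for Vcam1. The macrophage call ended without knockout replicate 3 or wild type replicate 3 (up to 0.120). The 16 endothelial markers had a median of +0.09 (limma camera adjusted p = 0.0216), against 0.00 for lists of like level, and the adjusted p was 0.505 with an estimated correlation. The endothelial members with the smallest p were Ramp2 (+0.44), Oit3 (+0.41), Flt1 (+0.21) and Kdr (+0.18), with 0 past the threshold (limma; 2 had an unadjusted p under 0.05). The mean level over this list was 1.75 in knockout and 1.64 in wild type liver, little above the array medians of 1.36 to 1.43. In wild type liver Flt1 (1.29) and Kdr (1.26) lay below those medians, near the floor of the measurement. The endothelial call ended without knockout replicate 2 or wild type replicate 1 (up to 0.121), and without knockout replicate 1 the median was +0.15. Flt1 had +0.14 without wild type replicate 1 and Kdr +0.28 without knockout replicate 1. The exact permutation test on the mean level gave p = 0.3 for the hepatocyte and macrophage lists and 0.1 for the endothelial list. Knockout replicate 2 lay above wild type replicate 1 in mean level for hepatocytes (5.66 against 5.52) and macrophages (1.94 against 1.92).

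The other 17 lists tested did not pass, with camera adjusted p from 0.0742 to 0.831. Of pathways, the actin filament regulators had a median of -0.03 (adjusted p = 0.733), but +0.09 with an adjusted p of 0.0130 after renewed quantile normalization. Both rest on the preset correlation, and on the values as deposited the adjusted p was 0.859 with an estimated correlation. In this list Tmsb10 had a log2 fold change of +0.69, Arpc2 -0.27, Capza1 -0.24 (-0.15 without wild type replicate 2) and Pfn1 -0.40 (-0.20 without knockout replicate 2, -0.26 without wild type replicate 3). The unfolded protein and amino acid response list had +0.09 (0.143), and +0.17 (0.0130) after renewed quantile normalization. As deposited, the adjusted p was 0.556 with an estimated correlation. When 1 array was left out, the median of this list ranged from +0.02 to +0.18 and its camera adjusted p from 0.0148 to 0.890. The interferon response list had -0.08 (0.125), and -0.09 (0.0362) after that normalization; its member Ifih1, a sensor of viral RNA, fell when adjusted over the list alone (-0.58). For the interferon list as deposited, the adjusted p was 0.505 with an estimated correlation. Medians were +0.05 for immediate early and heat shock genes (0.200), +0.09 for targets of erythropoietin and STAT5 (0.236), -0.09 for p53 targets and apoptosis (0.607) and -0.01 for cholesterol synthesis (0.761). Leaving out 1 array in turn gave medians from +0.01 to +0.13 for erythropoietin targets and from -0.10 to -0.01 for p53 targets. For cholesterol synthesis they ranged from -0.28 to +0.06. Of cell types, medians were +0.10 for lymphoid cells (0.0742), +0.06 for mesothelium and neighbouring organs (0.151), +0.02 for stellate and mesenchymal cells (0.200), +0.11 for the bile duct lineage (0.236), -0.04 for granulocytes and monocytes (0.415), +0.01 for megakaryocytes and platelets (0.579), +0.06 for stem and progenitor cells (0.632) and +0.04 for mast cells and basophils (0.831). The mean of the megakaryocyte list was -0.09 and that of the mast cell list -0.05, opposite in sign to their medians. Ppbp, a platelet chemokine gene, had -0.72, and Col1a1, a collagen gene, +0.38, neither past the threshold.

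**Figure D3:**
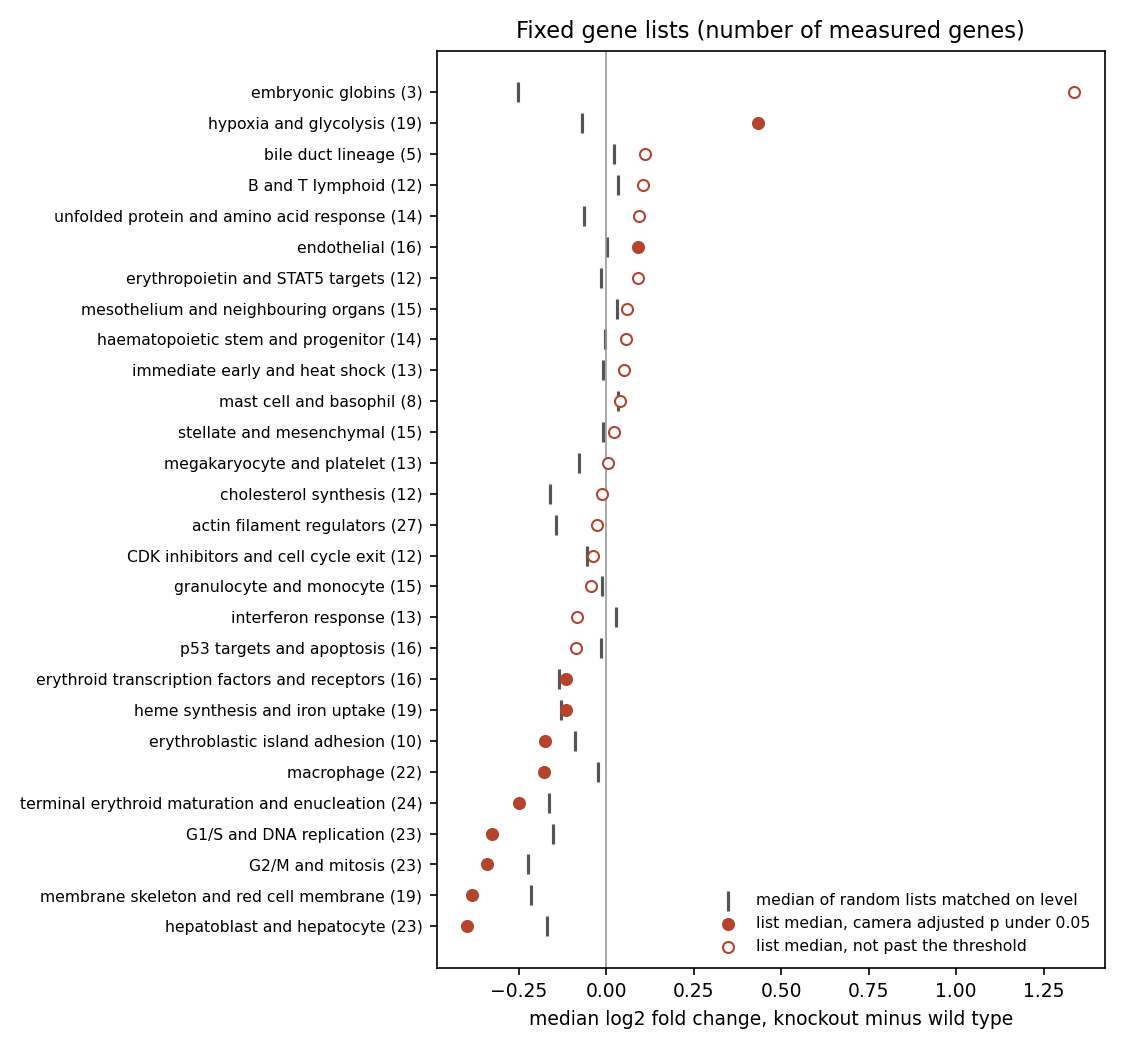
Median log2 fold change (knockout minus wild type, x axis) of the 28 tested gene lists, with the number of measured genes in brackets. Filled circles passed the camera threshold with the preset correlation, open circles did not, and vertical ticks give the median of random lists matched on level, which lie at -0.22 for the G2/M and the membrane lists.

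Genes that neighbour Tmod3 were examined because a targeted gene can carry flanking sequence of another strain. Of the 100 measured genes nearest to Tmod3, 50 on each side, 0 passed the threshold (limma; two-sided Fisher's exact p = 1). Besides Tmod3 only Car3 and Hpgd passed over all genes, so a count of 0 was likely in any stretch and cannot weigh flanking sequence. At an unadjusted p under 0.05, a count added after seeing the data, there were 14 (14.0%), against 9.0% of all other genes (two-sided Fisher's exact p = 0.111). With 100 genes on each side there were 34 of 200 (17%), against 8.95% (two-sided Fisher's exact p = 0.000281). Among the 100 nearest genes, Tex9 (-1.14) had the smallest p.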

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

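The tests of the patterns weighed here were all chosen or worded after the results were seen. Signal of Y-linked genes, which entered no list test, stood out on 1 array. Knockout replicate 2 read 4.21 for Eif2s3y, 2.41 for Uty and 1.84 for Kdm5d, above the highest wild type array for each gene (1.30 for Eif2s3y). The same array read 1.03 for Xist, where the other 5 arrays lay between 5.79 and 7.67. By these genes knockout replicate 2 came from a male embryo and the other 5 arrays from female embryos. Sex, which the labels do not give, thus differed within the knockout group, while all wild type embryos read as female.

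The hypoxia and glycolysis list was higher in knockout liver (median log2 fold change +0.43). Camera p-values at the preset correlation cannot weigh the causes below, because splits of the arrays that do not follow genotype also gave small ones. Knockout 1 with wild type 1 and 3, for example, gave a -log10 p of 4.14. A level-dependent difference between arrays is argued against as the whole cause by the list levels after renewed quantile normalization. They were 3.17 to 3.66 in knockout and 2.75 to 2.92 in wild type arrays (camera adjusted p = 6.30e-12). A single array, such as the only one with Y-linked signal, is argued against as the whole cause by the single levels. Each knockout array lay above each wild type array, as deposited and after that normalization. Without knockout replicate 2, the array with Y-linked signal, the median was +0.23, and the highest camera adjusted p without 1 array was 3.49e-05. Of the 10 splits of the 6 arrays, 1, the real one, gave a -log10 p as large (8.76, highest other 8.59 for knockout 1 with wild type 1 and 2; after renewed quantile normalization 12.6 and 6.55), and 10 splits are too few for a share under 0.05. Covariation of these genes between embryos stays open (estimated correlation 0.237). The camera adjusted p of 0.505 with an estimated correlation cannot weigh it, because 0 lists passed in that setting, whatever their correlation. The genotype, with the anemia and small livers in the labels, also stays open as an untested biological explanation.

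Of the lists, 9 were lower in knockout liver, where well expressed genes were lower in general, and all 9 lost the call with an estimated correlation (adjusted p = 0.505, for hepatocytes 0.539). As 0 lists of any kind passed in that setting, this loss does not set the 9 apart. A level-dependent difference between arrays is argued against as the whole cause for the G1/S list by its levels after quantile normalization. They were 3.59 to 3.66 in knockout and 3.74 to 3.83 in wild type arrays (camera adjusted p = 0.00549). The median shrank from -0.33 to -0.12, and the call ended among the 3988 genes with the highest means (0.124, median -0.34). Within the blocks of alike arrays the G1/S level differed by -0.12 and -0.42. The macrophage call held after quantile normalization (0.0130), but the levels overlapped (1.67 to 2.02 in knockout, 1.96 to 2.06 in wild type). This list is thus undecided. Its call ended among the 3988 genes (0.706, median -0.36 over the 7 left) and without knockout replicate 3 (0.120) or wild type replicate 3 (0.0501). The medians lay at the 0.91 (G1/S) and 0.08 percentile of random lists matched on level. Those lists hold genes drawn independently, while members here covaried (estimated correlation 0.334 and 0.172), which can make percentiles too extreme. The maturation, heme and transcription factor lists lay at the 10.3, 57.5 and 61.0 percentile and lost their calls after both normalizations and under the block of arrays with alike distributions, which is consistent with such a difference. The G2/M (5.98), membrane (1.92), island adhesion (15.9) and hepatocyte (0.08) lists cannot be told apart from it, because the matched lists and the 3 corrections did not all point one way. If all other cells kept their proportions to one another, a lower share of erythroid cells would raise the hepatocyte and macrophage lists, which were lower. Those proportions were not measured, so its part in these lists cannot be decided. For the erythroid lists a lower share also stays open, as it was not measured. The hepatocyte minus endothelial level cannot decide this, because it holds no erythroid gene. It differed by -0.38 after quantile normalization (-0.53 as deposited), with no overlap of the groups (exact permutation p = 0.1). That was less than their summed SDs (0.47 in knockout, 0.08 in wild type). Knockout replicate 3 weighed on it, with a hepatocyte level of 4.76 as deposited against 5.52 and 5.66 in the other knockout arrays. The endothelial list lay near the floor.

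Splits of the 6 arrays were also counted for each number of calls. For genes, 1 of the 10 splits called as many as the real 3, the highest other being 0. For pathway lists, 3 of the 10 splits called as many as the real 8, the highest other being 9, and for cell type lists 3 of the 10 called as many as the real 3, the highest other being 3. As 10 splits are too few for a share under 0.05, these counts leave chance undecided. The split of knockout 1, knockout 3 and wild type 1 against the rest, which follows the 90th percentile of the arrays, gave 9 pathway lists and 2367 genes with an unadjusted p under 0.05, against 1801 in the real split. With these arrays as a block, 6 pathway lists and 2 cell type lists passed.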

How the results depend on the processing

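Cyclic loess, the filter to the 3988 brightest genes by mean, its combination with quantile normalization, the block of arrays with alike distributions and the unadjusted count near Tmod3 were chosen after seeing the data. The Tmod3 log2 fold change stayed negative under every alternative run (adjusted p 0.00117 to 0.255), and without any 1 array it ranged from -3.41 to -2.88, losing its call in 4 of the 6 cases. The gene count of 3 became 7 after quantile normalization, 11 with array weights (wild type replicate 2 weighted 2.13, wild type replicate 1 weighted 0.52), 8 among the brightest genes, 9 with cyclic loess, 25 with quantile normalization of the brightest genes, and 5 with the block of alike arrays; without any 1 array it ranged from 0 to 95. The pathway list count of 8 became 5 after quantile normalization, 4 with 9969 genes kept by mean, 2 among the brightest genes, 5 with cyclic loess, 1 with quantile normalization of the brightest genes, 0 with an estimated correlation and 0 with fry; without any 1 array it ranged from 7 to 10. The cell type list count of 3 became 0 with 9969 genes kept, 0 among the brightest genes, 0 among these with quantile normalization, with an estimated correlation and with fry; without any 1 array it ranged from 1 to 5. Fry with either direction allowed gave adjusted p of 0.0353 for hypoxia, 0.0430 for G1/S, 0.0430 for stellate cells and 0.00246 for the kinase inhibitors. The actin regulator list turned from lower to higher, with adjusted p 0.0130 after quantile normalization and 0.0107 with cyclic loess. Near Tmod3, 14 genes in place of 0 were counted at an unadjusted p under 0.05. Numbers did not pair the samples (correlations of deviations 0.12, -0.08 and -0.09); with the replicate number as a block, 0 genes passed, the log2 fold change of Tmod3 was -3.06 (adjusted p = 0.0897), and the list counts of 8 and 3 were unchanged. Over single named genes other than Tmod3, 2106 values kept their direction and side of the threshold, 42 newly passed and 9 no longer did. Of these genes only Car3 and Hpgd passed in the main fit, so all 9 losses were theirs. Most of the 2106 values thus belong to genes without a call to lose. For Tmod3, 13 values kept direction and side and 5 no longer passed. Over single lists 472 values kept both, 16 newly passed, 78 no longer did and 2 turned. Those 78 losses fell on the 11 lists called in the main fit. The cause of these changes was not tested, including that of the rise to 95 genes without wild type replicate 1. Most genes lay near the array medians of 1.36 to 1.43, where signal over background limits what a difference can show.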

Other observations

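The tests in this part were chosen after the results were seen. Among well expressed genes (the 3988 genes with the highest means) after renewed quantile normalization, 25 genes passed the limma threshold, 13 higher and 12 lower. The genes named here were chosen after their values were seen. They are single genes, and no group of them was tested. Among the higher ones were Igfbp1 (log2 fold change +2.71 ± 0.42 SE), Hamp, which encodes the iron hormone hepcidin (+2.47 ± 0.46), and the metallothionein gene Mt1 (+1.25 ± 0.24). Among the lower ones were the fatty acid binding protein genes Fabp1 (-2.21 ± 0.36) and Fabp2 (-1.80 ± 0.35), the methyltransferase gene Bhmt (-1.34 ± 0.25) and the cytochrome P450 gene Cyp2c23 (-0.95 ± 0.18). Their adjusted p lay between 0.0209 and 0.0469, and in each gene all 3 knockout arrays lay on one side of all 3 wild type arrays. On the values as deposited, with all genes tested, none of these genes passed. The limma adjusted p was 0.202 for Igfbp1, 0.252 for Hamp, 0.299 for Mt1, 0.178 for Fabp1, 0.229 for Fabp2, 0.181 for Bhmt and 0.142 for Cyp2c23. Knockout replicate 3 read 3.07 for Hamp, against 5.42 and 5.09 in knockout replicates 1 and 2. For Fabp1 it read 4.09, against 6.06 and 4.93.

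Genes near Tmod3 held more small p-values than the median stretch of the genome at each of 3 widths tried. A hypothesis is that sequence of another strain was kept around the targeted gene. With 50 genes on each side, 10.3% of windows along the genome held as many genes with an unadjusted p under 0.05 (14), or 16.1% after quantile normalization (11 genes). With 25 on each side 10.5% did (8), or 34.2% after quantile normalization (5 genes). With 100 on each side 0.341% did (34 genes), or 1.49% after quantile normalization (26 genes). The number of 50 genes per side, set before the data were examined, leaves the hypothesis undecided, since chance placement and flanking sequence cannot be told apart from it.

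Probe sets that carry several gene names or none were not part of the gene tests. Of these 7064 probe sets, 0 passed the limma threshold and 520 (7.36%) had an unadjusted p under 0.05, against 9.17% of probe sets with 1 gene.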
